A study of Homo sapiens with 6 samples.

How the data were processed

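Poly(A) RNA-seq was analysed from HCT116, a human colorectal carcinoma cell line, 48 h after treatment with a negative control siRNA (NC) or with an siRNA against CPT2. Each group held 3 libraries, named by replicate numbers 1 to 3 in the labels. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented, primed with random hexamers and copied into double-stranded cDNA by a procedure that names no strand marking. How the authors' counting treated strand is not given in the sources used here. Reads of overlapping genes are therefore uncertain, on the same strand or on opposite strands.

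The authors deposited raw read counts per gene and library, whole numbers that had not been normalized. The values beside them are named FPKM in the file headers, which do not say from which gene models and library sizes the authors computed them. The same deposited table holds the p-value, the log2 fold change and the call (up, down or normal) of the authors' DESeq2 comparison, per the file headers. Those calls were matched exactly by an unadjusted p under 0.01 with a fold of 1.5 in all 13635 genes that had a p-value. The genome build GRCh38 and the tools HISAT2, TopHat2, Bowtie2, StringTie, DESeq2 and edgeR are named in the submitters' processing notes, without versions or roles.

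The table had 24154 genes after 17 stray lines with no gene ID or values were left out. Of these, 19974 carried an Ensembl ID, all of which matched the GENCODE 29 annotation of GRCh38, and 19922 were protein coding. The remaining 4180 were new loci of the authors without a symbol, which held 5.32% to 7.18% of the counts of a library and stayed in the library sizes and tests. Total counts were 28353790 to 29449380 per library. Coordinates, transcript length and transcript GC content were taken from GENCODE 29 on GRCh38, with the longest transcript standing for each gene.

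Counts were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr (15302 genes kept), TMM scaling and the quasi-likelihood F-test with robust dispersion estimation. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM were computed on TMM-scaled library sizes, errors are SD over n = 3 libraries unless SE is named, and all log2 fold changes are knockdown over control. For 35 gene lists fixed before the data were examined, the camera test of limma 3.58.1 compared the members with all other tested genes on log2 CPM (prior count 2). It used a preset inter-gene correlation of 0.01 and was adjusted over the 33 lists with at least 5 tested members. The list tests were repeated with a correlation estimated from the data and with limma's fry. The lists covered fatty acid and mitochondrial metabolism, stress responses, cell cycle, signalling, ribosomes, markers of other cell types and signs of RNA quality.

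The rule for named genes was also fixed beforehand. It took CPT2, up to 10 of the largest rises and 10 of the largest falls among called genes with full separation of the groups and a mean of at least 1 CPM, and up to 3 called members of each list. It always took CPT1A, SLC25A20, ACADVL, ACADM, HADHA and HADHB. ZNF468, TMED7-TICAM2, TMED7, HERPUD1 and every list member given as an example were chosen after their values were seen, the examples for having the smallest p-values of their list.

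Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter, a filter at 1 CPM in 3 libraries with a mean of 5 CPM, the replicate number as a block, leaving out each library, limma-trend on log2(FPKM + 1), an adjusted p of 0.01 and glmTreat against a fold of 1.2. Alternatives chosen after seeing the data were Ensembl genes alone, offsets from a loess of each library on transcript GC and length, the sum of genes whose exons overlap on the same strand (2397 genes in 877 groups), sample quality weights in limma-voom, and combinations of these. For the stress response lists, the list median was also set among 10000 random lists, each member replaced by a gene outside the list with a mean log2 CPM over 2, within 1.5 percentage points of its GC content and 0.4 of its log2 length.

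The tests were checked on simulated data, drawn from the real means, library sizes and dispersions with 200 genes changed by known folds. In 15094 simulated genes for the CPT2 knockdown against NC, without a GC trend, edgeR recovered 84.6% of 4-fold, 32.3% of 2-fold and 6.15% of 1.5-fold changes and called 3 unchanged genes, where DESeq2 called 29. With the libraries' GC trend put into 13077 genes, edgeR with the GC and length offsets recovered 100% of 4-fold, 67.2% of 2-fold and 42.4% of 1.5-fold changes and called 9 unchanged genes. Without the offsets, edgeR there recovered 95.5%, 40.3% and 13.6% and called 11 unchanged genes. That simulation used the lower dispersions left after GC and length correction, so its rates cannot be compared with those of the simulation without a trend. Sample quality weights called 908 unchanged genes in the same simulation. No pair of libraries matched within sampling noise: the chi-square per degree of freedom between libraries was 15.0 or more.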

Results

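The transcriptome of HCT116 colorectal carcinoma cells was measured by poly(A) RNA-seq after 48 h with a control siRNA (NC, n = 3) or an siRNA against CPT2 (n = 3). CPT2 encodes carnitine palmitoyltransferase 2, the inner mitochondrial membrane enzyme that releases long-chain acyl groups from carnitine for fatty acid oxidation. Libraries held 28353790 to 29449380 counts. The comparison asks how gene expression differs when CPT2 is targeted. Transcripts encoded by mitochondrial DNA made up 10.5%, 10.8% and 10.002% of counts in NC replicates 1, 2 and 3, and 17.0%, 15.6% and 8.99% in CPT2 knockdown replicates 1, 2 and 3. CPT2 knockdown replicate 1 stood apart from the other libraries on the first principal component, which held 53.2% of the variance: its score was 76.6, against -44.6 to 16.03 in the others.

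CPT2 counts were lower in all 3 knockdown libraries than in any control, with a fitted difference of 26.5%. CPT2 (ENSG00000157184) is a protein-coding gene on the plus strand of chromosome 1, positions 53196429 to 53214197 (GRCh38). Its level was 27.1 ± 3.01 CPM in controls and 19.9 ± 1.23 CPM after the knockdown (SD, n = 3 each). The log2 fold change was -0.44 (SE 0.17, 95% interval -0.83 to -0.06), so that the interval leaves out a fall by 1 on the log2 scale. Raw counts were 709, 881 and 911 in NC replicates 1 to 3, and 492, 597 and 553 in knockdown replicates 1 to 3. The difference did not pass over all genes (edgeR, adjusted p = 0.34), and an exact 2-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 allow. In the authors' deposited table, CPT2 had a log2 fold change of -0.44 and an unadjusted p of 0.0118 and was called normal. Among 501 genes of similar transcript GC content and length, the median log2 fold change was -0.40, and CPT2 lay at the 42.1st percentile. By library it lay at the 83.8th, 6.39th and 21.2nd percentiles in knockdown replicates 1, 2 and 3. With offsets for GC content and length, chosen after seeing the data, the CPT2 log2 fold change was 0.01 (SE 0.20, adjusted p = 0.98). Leaving out CPT2 knockdown replicate 1 as well, it was -0.26 (SE 0.13, edgeR adjusted p = 0.589). Over all 21 alternatives the adjusted p ranged from 0.0235 to 0.984.

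**Figure D1:**
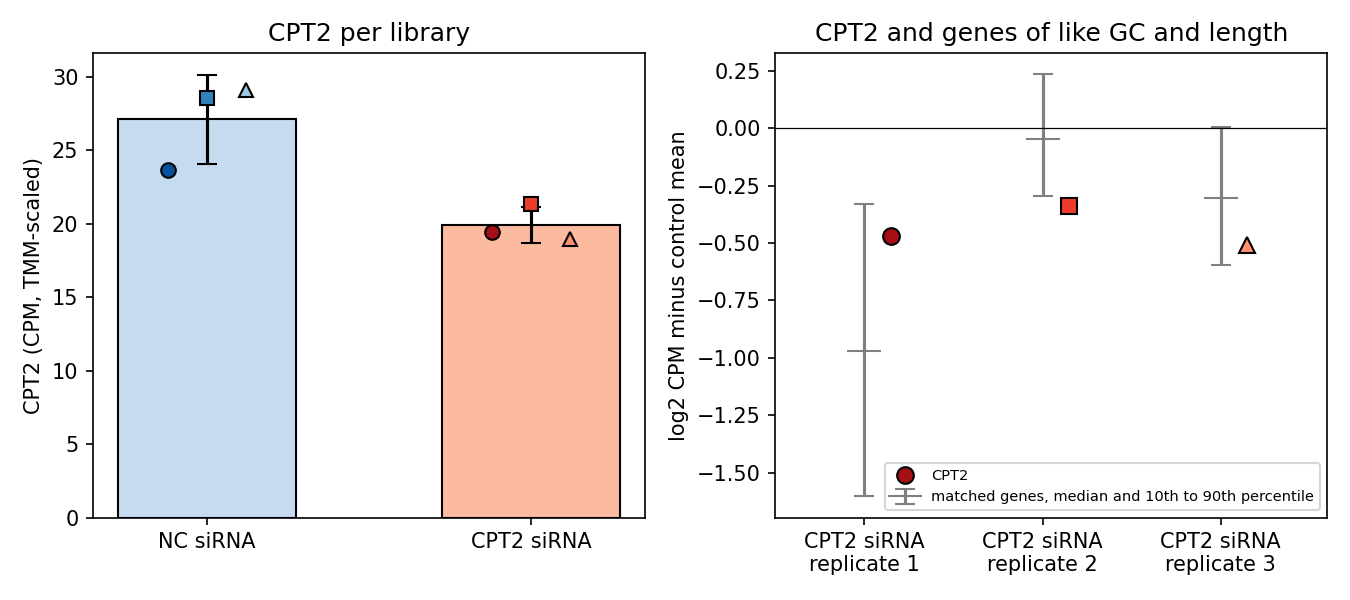
Left, CPT2 in TMM-scaled CPM, with bars for the mean of n = 3, error bars for the SD and a point per library. Right, log2 CPM of CPT2 minus the control mean in each knockdown library (coloured points), beside the median and the 10th to 90th percentiles of 501 genes of like GC content and length (grey): CPT2 lay above the matched median in replicate 1 (-0.47 against -0.97) and below it in replicates 2 and 3.

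ZNF320 and TICAM2 were the only genes called between the groups by edgeR among 15302 tested, and both share exons with a neighbour whose counts differed in the opposite direction. ZNF320, a zinc finger protein gene, rose from 2.33 ± 0.198 to 38.8 ± 2.19 CPM (log2 fold change 4.05, SE 0.19, adjusted p = 9.6e-05, n = 3 each). TICAM2, an adaptor gene of Toll-like receptor 4 signalling, fell from 3.95 ± 1.18 to 0.255 ± 0.0596 CPM (log2 fold change -3.93, SE 0.38, adjusted p = 0.0237, n = 3 each). ZNF320 (ENSG00000182986) lies on the minus strand of chromosome 19 at 52863790 to 52897693, overlapping ZNF468 (ENSG00000204604) at 52838008 to 52890375. ZNF468 had 57.1 ± 1.78 CPM in controls and 9.97 ± 5.16 CPM after the knockdown, and did not pass (edgeR, adjusted p = 0.27). ZNF468 passed by DESeq2 (adjusted p = 3.95e-10), and by edgeR without a filter on low counts (0.0376), without CPT2 knockdown replicate 1 (0.0142) or 2 (0.0106) and with GC and length offsets (0.00394). TICAM2 (ENSG00000243414) lies on the minus strand of chromosome 5 at 115578650 to 115602479, inside the readthrough gene TMED7-TICAM2 at 115578642 to 115626161. TMED7-TICAM2 had counts of 0, 89 and 0 in NC replicates 1 to 3, and 93, 153 and 156 in knockdown replicates 1 to 3. TMED7, which overlaps the same readthrough gene, had 81.3 ± 17.9 CPM in controls and 43.8 ± 21.3 CPM after the knockdown and did not pass (edgeR, adjusted p = 0.34). Summed over each pair, the log2 fold change was -0.29 (SE 0.15) for ZNF320 with ZNF468 and 0.052 (SE 0.24) for TICAM2 with TMED7-TICAM2. When all genes with overlapping exons on the same strand were summed, edgeR called 0 genes at an adjusted p of 0.05, and 2423 had an unadjusted p under 0.05. In the authors' FPKM, ZNF320 was 2.57 ± 0.625 in controls and 6.07 ± 0.793 after the knockdown, a fold of 2.36 against the 16.6 of the counts. The TICAM2 call was lost without NC replicate 1 (adjusted p = 0.172), without NC replicate 3 (0.149) and without CPT2 knockdown replicate 3 (0.223).

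**Figure D2:**
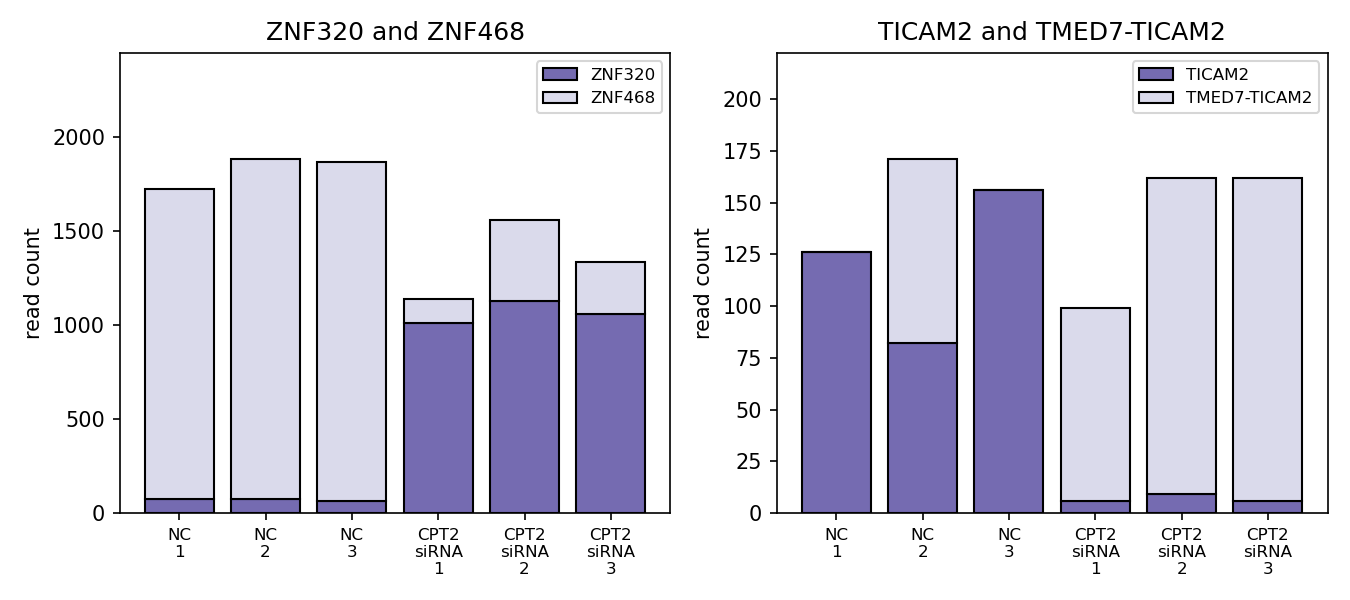
Raw read counts per library (bars start at 0), stacked for ZNF320 with ZNF468 (left) and TICAM2 with TMED7-TICAM2 (right). ZNF320 held 66 to 76 counts in the NC libraries and 1010 to 1126 after CPT2 siRNA, while the sum of the pair went from 1726 to 1882 in NC down to 1138 to 1556.

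Few other genes were called by any planned test that treats the libraries as unpaired and equally weighted. The planned edgeR fit with the replicate number as a block called 633 genes. DESeq2 called 17 genes, 11 higher and 6 lower, with ZNF320 and TICAM2 among them, and limma-voom called ZNF320 alone. In simulated data of the same spread with 200 changed genes but without the GC trend, DESeq2 called 29 unchanged genes, edgeR 3 and limma-voom 4. DESeq2 there also recovered 86.2% of 4-fold, 55.4% of 2-fold and 18.5% of 1.5-fold changes. The 29 therefore do not measure how many of its 17 calls are false. By edgeR, 2215 genes had an unadjusted p under 0.05, of which 1405 were higher and 810 lower, and the groups did not overlap in 24.4% of genes, where chance gives 10%. Setting NC replicate 1 with knockdown replicates 1 and 3 against the other 3 libraries gave 2344 such genes and no overlap in 24.9%. The count of 2215 moved to 1324, 503 and 1224 without NC replicates 1, 2 and 3, and to 5615 and 1436 without CPT2 knockdown replicates 2 and 3. The authors' deposited table calls 378 genes up and 188 down on unadjusted p-values. Adjusted by the Benjamini-Hochberg method over the 13635 genes tested there, 17 of those p-values were under 0.05.

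Fold changes followed transcript GC content, with GC-rich genes higher and AT-rich genes lower in the knockdown. The median log2 fold change was -0.41 in the 1321 genes of the lowest GC decile (30.2% to 38.6%) and 0.48 in the 1321 genes of the highest (62.0% to 74.7%). Across 13207 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.68, and it was 0.48 without CPT2 knockdown replicate 1. Medians from the lowest to the highest decile ran from -1.02 to 0.81 in CPT2 knockdown replicate 1, from -0.29 to 0.44 in replicate 3 and from -0.04 to 0.09 in replicate 2. NC replicate 2 ran the other way, from 0.18 to -0.17. The slopes of the libraries on GC content did not differ between the groups beyond their spread (exact 2-sided permutation p = 0.3, n = 3 each; 0.1 is the smallest possible). The genes called up in the authors' deposited table had a median GC content of 61.4% and those called down 41.7%, against 48.7% for all genes tested there.

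**Figure D3:**
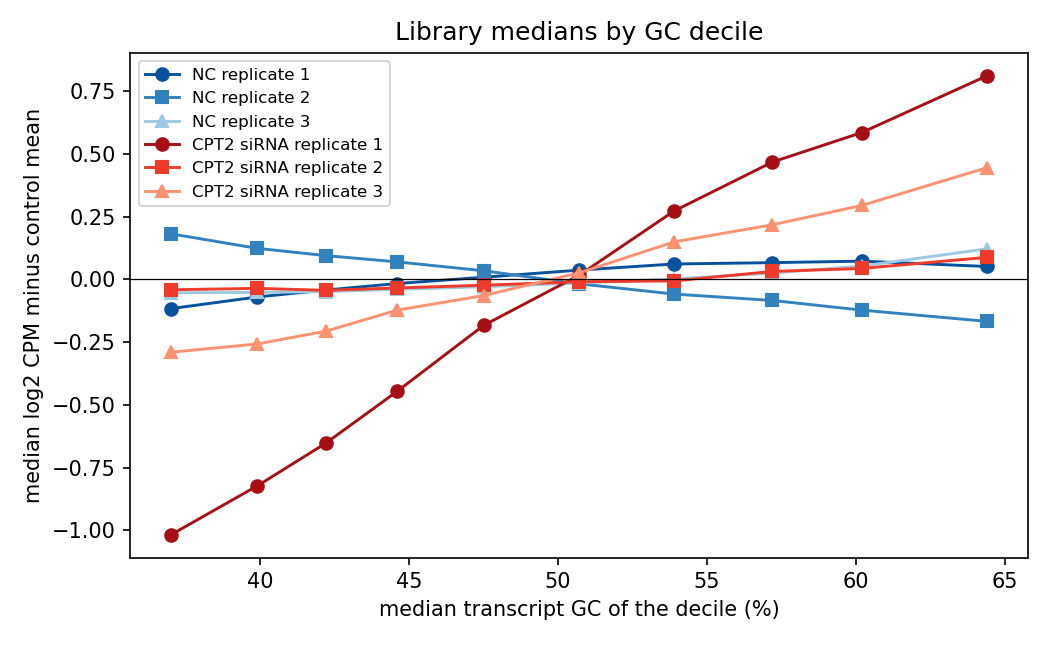
Median of log2 CPM minus the control mean (y axis) in each decile of transcript GC content (x axis, %), with a line per library, NC in blue and CPT2 siRNA in red. CPT2 knockdown replicate 1 spans -1.02 to 0.81, while replicate 2 stays between -0.04 and 0.09.

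Genes of the carnitine shuttle and mitochondrial fatty acid oxidation did not shift as a group. None of the 30 tested members passed by edgeR, over all genes or adjusted over the list alone, and the median log2 fold change was 0.02 (17 higher, 13 lower, camera adjusted p = 0.943). CPT1A, the outer membrane partner of CPT2, had 110.9 ± 11.0 CPM in controls and 91.1 ± 5.99 CPM after the knockdown (log2 fold change -0.28, SE 0.14). SLC25A20, the carnitine-acylcarnitine carrier, had a log2 fold change of -0.13 (SE 0.21), which was 0.0235 without NC replicate 1, -0.27 without NC replicate 3, -0.24 and -0.066 without CPT2 knockdown replicates 1 and 3, and -0.29 with GC and length offsets. The values were 0.44 (SE 0.20) for ACADVL and -0.40 (SE 0.26) for ACADM, which encode the very long-chain and medium-chain acyl-CoA dehydrogenases. Without CPT2 knockdown replicate 1 they were 0.20 and -0.17, without replicate 2 ACADM had -0.70, and with GC and length offsets they were 0.081 and -0.24. ACADVL passed with sample quality weights (0.35, adjusted p = 0.0353). HADHA and HADHB, the subunits of the trifunctional protein, had 0.19 (SE 0.15) and -0.19 (SE 0.15). HADHA had 0.081 without CPT2 knockdown replicate 1 and 0.29 without replicate 2, and HADHB -0.0996 without NC replicate 1, -0.13 without CPT2 knockdown replicate 1 and -0.025 with GC and length offsets. Their genes overlap on opposite strands of chromosome 2, where reads cannot be told apart without strand. On library size alone, ACADVL had 0.28, SLC25A20 -0.27, HADHA 0.045 and HADHB -0.32, with a median of -0.13 over all genes. The edgeR adjusted p of these 6 genes lay between 0.338 (ACADVL) and 0.733 (SLC25A20).

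Unfolded protein response genes of the endoplasmic reticulum were lower as a group after the knockdown in the planned camera test, but not with an estimated correlation. The median log2 fold change of the 27 members was -0.19, with 18 lower and 9 higher (camera adjusted p = 0.0207, and 0.898 with an estimated correlation, here 0.0437). By edgeR no member passed over all genes, and adjusted over the list alone 1 did, HERPUD1, a component of endoplasmic reticulum-associated degradation. HERPUD1 had 96.7 ± 1.12 CPM in controls and 60.6 ± 6.94 CPM after the knockdown (SD, n = 3 each). Its log2 fold change was -0.67 (SE 0.14, edgeR adjusted p = 0.34 over all genes and 0.0337 over the list). DESeq2 called it over all genes (log2 fold change -0.68, adjusted p = 0.0182). In simulated data with 200 changed genes, DESeq2 also called 29 unchanged genes, which gives no error rate for this call. CANX, a lectin chaperone, had -0.59 (SE 0.19), EDEM1 had -0.59 (SE 0.19) and HSPA5, the chaperone BiP, had -0.38 (SE 0.12), none of which passed by edgeR. The list median was lower than in every control in all 3 knockdown libraries, at -0.25, -0.25 and -0.24 against the control mean. The list was not past the threshold without NC replicate 1 (adjusted p = 0.0762), NC replicate 3 (0.0655) or CPT2 knockdown replicate 2 (0.263). Nor was it past the threshold with the replicate number as a block. With the GC and length trend removed, its adjusted p was 0.00278 (adjusted p = 0.258 with an estimated correlation) and the median -0.17. As counted, the list median lay at the 8.25th percentile of 10000 random lists of like GC content and length, and at the 41.7th, 0th and 0.35th in knockdown replicates 1, 2 and 3. In NC replicates 1, 2 and 3 it lay at percentiles 96.1, 10.6 and 94.6. Members of the random lists were drawn singly, without the co-variation of a real list, so these percentiles are not p-values. The median of 6 nuclear-retained and intron-retaining transcripts, taken as a sign of RNA quality, was -0.96, -0.13 and -0.33 in knockdown replicates 1 to 3 and -0.11, 0.21 and -0.089 in NC replicates 1 to 3. With the GC and length trend removed it was 0.085, -0.085 and -0.030 in knockdown replicates 1 to 3.

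Cytosolic ribosomal protein genes were higher as a group in the planned camera test, but not with an estimated correlation. Of 56 members, 53 had a positive log2 fold change, with a median of 0.30 (camera adjusted p = 1.19e-06, and 0.898 with an estimated correlation, here 0.65). None passed by edgeR over all genes or adjusted over the list alone. RPS15, which DESeq2 called over all genes, had a log2 fold change of 0.82 (SE 0.17) by edgeR, RPL28 0.90 (SE 0.24) and RPS2 0.68 (SE 0.18). By library, the list median against the control mean was 0.48, 0.07 and 0.37 in knockdown replicates 1, 2 and 3. In NC replicates 1, 2 and 3 it was 0.10, -0.21 and 0.11, so that knockdown replicate 2 lay within the controls. The RNA quality transcripts had medians of -0.96, -0.13 and -0.33 in these knockdown libraries and -0.11, 0.21 and -0.089 in these controls. After removal of the GC and length trend they had 0.085, -0.085 and -0.030 in these knockdown libraries. With the GC and length trend removed, 44 of the 56 ribosomal genes were higher, with a median of 0.22 (adjusted p = 0.000602; adjusted p = 0.914 with an estimated correlation).

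Genes for the respiratory chain were higher in some knockdown libraries. The 13 mitochondrially encoded protein genes had a median log2 fold change of 0.61 and all were higher (camera adjusted p = 0.00977, and 0.898 with an estimated correlation, here 0.79). MT-ND2, a complex I subunit, had 5017 ± 91.2 CPM in controls and 9134 ± 3885 CPM after the knockdown, which did not pass by edgeR. The list median against the control mean was 1.04 and 0.71 in knockdown replicates 1 and 2 and -0.05 in replicate 3. The list was not past the threshold without CPT2 knockdown replicate 1 (adjusted p = 0.0744) or replicate 2 (0.282). Of the 56 nuclear-encoded oxidative phosphorylation genes, 45 were higher, with a median of 0.20 (camera adjusted p = 0.00977, and 0.918 with an estimated correlation, here 0.412). NDUFB10 had a log2 fold change of 0.61 (SE 0.17), ATP5PF 0.61 (SE 0.18) and NDUFS8 0.70 (SE 0.22). None of the members passed by edgeR over all genes or adjusted over the list alone. Its median against the control mean was 0.28, -0.06 and 0.32 in knockdown replicates 1 to 3, and 0.10, -0.18 and 0.05 in NC replicates 1 to 3. The RNA quality transcripts had -0.96, -0.13 and -0.33 in the former and -0.11, 0.21 and -0.089 in the latter. After removal of the GC and length trend they had 0.085, -0.085 and -0.030 in knockdown replicates 1 to 3. The nuclear-encoded list was not past the threshold without NC replicate 2 (0.194) or CPT2 knockdown replicate 3 (0.205). With the GC and length trend removed, the mitochondrially encoded list had 12 of 13 genes higher and a median of 0.48 (adjusted p = 0.0539), with 0.94, 0.61 and -0.36 in knockdown replicates 1 to 3. The nuclear-encoded list then had 35 of 56 higher and a median of 0.098 (adjusted p = 0.21), with 0.18, -0.091 and 0.14.

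Nuclear-retained and intron-retaining transcripts, taken as a sign of RNA quality, were lower in the knockdown as counted. Of the 15 members, 6 were among the deposited genes, and MALAT1 and NEAT1 were not. The median GC content of these 6 was 36.6%, within the lowest GC decile (30.2% to 38.6%). That decile had a median of -1.02 in CPT2 knockdown replicate 1, so the list cannot be told apart from the GC trend. All 6 tested members had negative log2 fold changes, with a median of -0.44 (camera adjusted p = 0.0304, and 0.898 with an estimated correlation, here 0.934). NKTR had -0.56 (SE 0.23) and SON -0.50 (SE 0.22), and none passed by edgeR over all genes or adjusted over the list alone. The list median against the control mean was -0.96 in CPT2 knockdown replicate 1, -0.13 in replicate 2 and -0.33 in replicate 3. The list was not past the threshold without NC replicate 2 (adjusted p = 0.0698), CPT2 knockdown replicate 1 (0.0744) or CPT2 knockdown replicate 3 (0.0752), and with the GC and length trend removed the median was -0.025 (adjusted p = 0.907). Of 22 alternatives, it passed in 6.

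**Figure D4:**
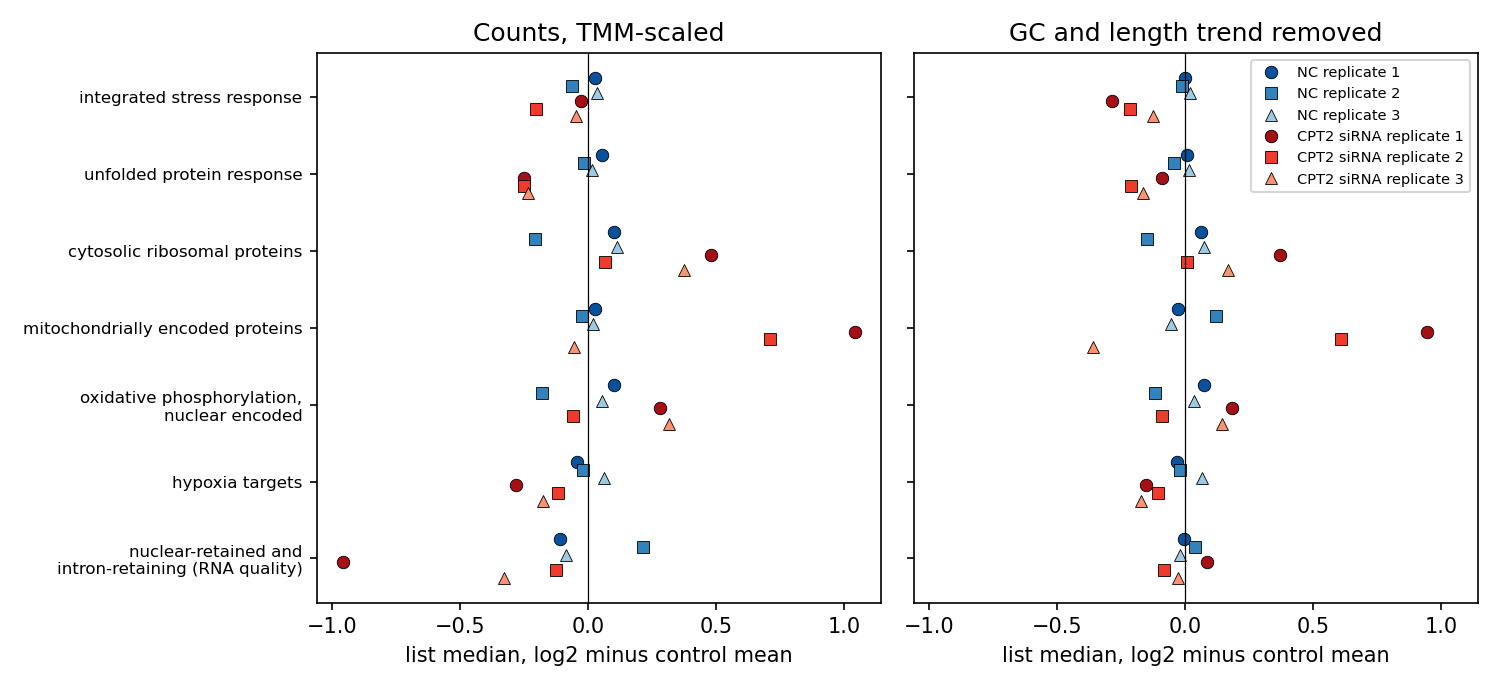
Median over list members of log2 expression minus the control mean (x axis) for 7 gene lists, with a point per library, NC in blue and CPT2 siRNA in red, on TMM-scaled counts (left) and with the GC and length trend removed (right). The unfolded protein response list is lower than in every control in all 3 knockdown libraries in both panels, and the mitochondrially encoded list is at 1.04, 0.71 and -0.05 in knockdown replicates 1 to 3 on the left.

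The other 28 lists tested did not pass. Among stress responses, the ATF4 targets of the integrated stress response had a median log2 fold change of -0.10 over 36 genes, 20 lower and 16 higher (camera adjusted p = 0.182). Hypoxia targets had -0.13 over 25 genes (0.143). The integrated stress response passed without NC replicate 2 (adjusted p = 0.0437) and without CPT2 knockdown replicate 1 (0.029). NRF2 targets and glutathione genes had a median of 0.21 (0.432), p53 targets -0.17 (0.432) and apoptosis regulators -0.19 (0.26). In lipid metabolism, the camera adjusted p was 0.943 for peroxisomal oxidation, 0.847 for PPAR targets, 0.943 for fatty acid synthesis, 0.563 for cholesterol synthesis, 0.665 for lipid droplet turnover and 0.563 for ferroptosis genes. It was 0.939 for the tricarboxylic acid cycle and 0.432 for glycolysis. Proliferation genes gave 0.943 for G1/S and DNA replication, 0.432 for G2/M, 0.563 for replication-dependent histones and 0.234 for ribosome biogenesis and MYC targets. Signalling and identity lists gave 0.26 for interferon-stimulated genes, 0.894 for NF-kB, 0.943 for Wnt targets, 0.847 for epithelial-mesenchymal transition, 0.939 for TGF-beta targets, 0.943 for immediate early genes, 0.939 for autophagy and lysosome and 0.337 for colonocyte and goblet differentiation. Median, mean and camera direction did not share a sign for peroxisomal oxidation, PPAR targets, the tricarboxylic acid cycle, G1/S genes, Wnt targets, immediate early genes and fibroblast markers, whose medians lay between -0.093 (PPAR targets) and -0.0068 (fibroblast markers). Markers of other cell types were sparse: 8 of 16 fibroblast, 15 of 19 blood and immune, 15 of 16 liver and 11 of 15 embryonic kidney and neural markers averaged under 1 CPM. The adjusted p was 0.943 for fibroblast and 0.422 for kidney and neural markers, and the blood and liver lists had too few tested members (4 and 1) for a list test. No list other than that of the unfolded protein response had a member that passed by edgeR adjusted over the list alone.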

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

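The GC and length corrections, the sums over overlapping genes, the quality weights and the Ensembl-only fit were chosen after seeing the data; the other alternatives were fixed before. The planned edgeR test called 2 genes, 1 higher and 1 lower. DESeq2 called 17 (11 higher, 6 lower), limma-voom 1 (0 lower), the stricter filter 1 (0 lower), no filter 2 lower, an adjusted p under 0.01 gave 1, and limma-trend on FPKM 0 (0 higher, 0 lower), where 2055 genes had an unadjusted p under 0.05. RLE and upper-quartile factors, library size alone, Ensembl genes alone and glmTreat each called 2, although library size alone moved the median log2 fold change of all genes to -0.13. Leaving out 1 library gave 1 to 5 genes (1 to 3 higher, 0 to 2 lower). GC and length offsets gave 3 (2 lower), and 4 (3 lower) without CPT2 knockdown replicate 1. Summing overlapping genes gave 0 (0 higher, 0 lower), because the group of ZNF320 then had -0.26 and that of TMED7-TICAM2 -0.81. Quality weights gave 2915 (1607 higher, 1308 lower), among them CPT2 (-0.50, adjusted p = 0.0235). The labels do not say whether the replicate numbers pair the samples, and the counts did not settle it. Correlations of deviations between same-numbered libraries were 0.25, 0.363 and 0.00651. NC replicate 3 correlated more with CPT2 knockdown replicate 1 (0.0911) than with its own number, while every other library correlated best with its own number. With the replicate block, edgeR called 633 genes (314 higher, 319 lower), and with GC and length offsets as well 669 (386 higher, 283 lower). The block lowered the common biological coefficient of variation from 23.4% to 18.6%. In data simulated without paired samples and without a GC trend, the blocked fit called 3 unchanged genes. It was not run on data simulated with the GC trend. These 3 therefore cannot say whether the 633 calls come from pairing. HERPUD1 passed with the block (adjusted p = 0.0479), while the unfolded protein response list was not past the threshold (0.057). The cause of these differences was not tested, apart from the summed genes.

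CPT2 was lower in 20 of 21 alternatives, from -0.58 to -0.02. It turned to 0.011 with GC and length offsets, which take out the trend of genes like it. With those offsets and without CPT2 knockdown replicate 1 it was -0.26. SLC25A20 ranged from -0.27 to 0.0235 (without NC replicate 1) when 1 library was left out, and ACADVL turned to -0.0056 with GC and length offsets without CPT2 knockdown replicate 1. CPT1A, ACADM, HADHA and HADHB kept their direction and side of the threshold in all 21. Of the gene lists, 5 passed in the planned camera test, 0 with an estimated correlation and 0 by fry, with or without the GC and length trend. Leaving out 1 library gave 3 to 4 lists, and 3 to 5 with the trend removed, and all other alternatives 4 or 5. At this depth and spread, simulated 1.5-fold changes were mostly missed by edgeR (6.15% recovered). In the simulation with the GC trend put in, 13.6% were recovered, at the lower dispersions left after GC and length correction.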

Other observations

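All tests of explanations in this part, and the bounds they were held to, were chosen after the results were seen. With the GC and length trend removed, 30 of the 36 integrated stress response genes were lower after the knockdown, where as counted 20 were lower and 16 higher. The median log2 fold change was -0.19 with the trend removed and -0.10 as counted. The camera adjusted p was 0.182 as counted and 1.08e-05 with the trend removed, where it was 0.258 with an estimated correlation. Over all alternatives it ranged from 1.17e-06 to 0.898. With the offsets, DDIT3, which encodes the stress-induced transcription factor CHOP, had -1.05 (SE 0.22), CHAC1 -1.05 (SE 0.29), SESN2 -0.72 (SE 0.18) and ATF3 -0.56 (SE 0.14). As counted they had -0.80, -0.52, -0.46 and -0.54, and no member passed adjusted over the list alone. With the GC and length trend removed, these 4 passed adjusted over the list alone, and none of the 36 passed over all genes (edgeR with offsets). Hypoxia targets also passed in that version (18 of 25 lower, median -0.17, adjusted p = 0.0374, and 0.596 with an estimated correlation), but not without NC replicate 3 (0.159), CPT2 knockdown replicate 2 (0.0657) or CPT2 knockdown replicate 3 (0.113). Of the 27 immediate early genes, 13 were higher and 14 lower as counted (median -0.023, camera adjusted p = 0.943), and 10 were higher and 17 lower with the trend removed (median -0.13). The smallest p-values as counted were those of FOSB (log2 fold change 1.15, SE 0.29) and JUNB (0.53, SE 0.15), and none passed by edgeR.

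Lower CPT2 counts and the GC trend of the fold changes are the first pattern. A GC bias of single libraries is a candidate source of the trend, since controls differed from each other along GC content as well (rho up to 0.533 in size, for NC replicate 2 against the other controls). A response to the knockdown was not shown, as the library slopes overlapped between the groups (exact permutation p = 0.3, n = 3 each). On deviations from the mean of all libraries, the slope of CPT2 knockdown replicate 2 was -0.114 log2 per 10 percentage points of GC. This was below NC replicates 1 (-0.0983) and 3 (-0.0966). The GC deciles were set against the control mean instead, so only the order of these slopes can be read, and not their sign. With 3 libraries per group, the test cannot exclude a response. The CPT2 value may come from that trend, since it lay at the 42.1st percentile of genes of like GC content and length. An effect of the siRNA on CPT2 cannot be told apart from it: with offsets and without CPT2 knockdown replicate 1 the log2 fold change was -0.26 (SE 0.13), and CPT2 lay at the 83.8th, 6.39th and 21.2nd percentiles in replicates 1, 2 and 3. A fall by 1 on the log2 scale lies outside the interval with offsets (-0.44 to 0.46) and without them (-0.83 to -0.06).

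ZNF320 and TICAM2 form the second pattern. Reads assigned to one or the other of 2 overlapping genes are a candidate explanation for both calls, since the summed log2 fold change was -0.29 for ZNF320 with ZNF468 and 0.052 for TICAM2 with TMED7-TICAM2. The count per FPKM of ZNF320 rose 6.3-fold between the groups, more than in 99.99% of 12736 genes, while that of TICAM2 rose 1.08-fold. Another transcript of each locus in use after the knockdown stays open, since the FPKM differed as well (folds of 2.36 and 0.0555) and values per gene cannot separate this from read assignment. Of the 10 splits of the 6 libraries, 1, the real one, gave as many as 2 genes (highest other 1), and with offsets 1 gave as many as 3 (highest other 2), too few splits for a share under 0.05.

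Lower stress response genes are the third pattern. The values argue against the GC and length trend as the whole cause, for the unfolded protein response in knockdown replicates 2 and 3 alone. Set against 10000 random lists of like GC content and length, the median as counted lay below every control by more than their SD in all 3 knockdown libraries for the integrated stress response. For the unfolded protein response it did so in 2, replicates 2 and 3, while CPT2 knockdown replicate 1 was like its matched lists (41.7th percentile). Over all libraries the percentiles were 0.02 and 8.25. In NC replicates 1, 2 and 3 they were 28.6, 25.5 and 94 for the integrated stress response and 96.1, 10.6 and 94.6 for the unfolded protein response. The random lists lack the co-variation of a real list, so no percentile is a p-value. With the trend removed both lists passed by camera at the preset correlation (adjusted p = 1.08e-05 and 0.00278). The integrated stress response was taken up because it passed in that version, so its p there is not separate evidence against the trend. As counted it had not passed (0.182, but 0.0437 without NC replicate 2 and 0.029 without CPT2 knockdown replicate 1). The unfolded protein response had passed as counted (0.0207). The same counts of libraries argue against 1 deviating library, as do the medians of the knockdown library closest to the controls with the trend removed (-0.13 and -0.091, below every control; -0.027 and -0.24 as counted, where CPT2 knockdown replicate 2 alone lay below every control for the integrated stress response), and leaving out 1 library with the trend removed kept the call for the integrated stress response (1.17e-06 to 0.000301) but ended that of the unfolded protein response without CPT2 knockdown replicate 2 (0.0658; as counted 0.263, and 0.0762 and 0.0655 without NC replicates 1 and 3). An effect of the CPT2 siRNA may underlie the pattern as a hypothesis. It cannot be told apart from other differences between the groups, because the samples allow only this comparison. The shift itself is also uncertain, as neither list passed by camera with an estimated correlation (adjusted p = 0.258 for both). Of the 10 splits, 1 gave as many as the 5 lists of the planned test (highest other 4), and 3 gave as many as the 4 lists with the trend removed (highest other 6), too few splits for a share under 0.05.

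Sample quality weights gave 2915 genes, and 2 of the 10 splits gave as many; the highest other split, which groups CPT2 knockdown replicate 2 with NC replicates 1 and 3, gave 4068, and in simulated data with the GC trend of the libraries these weights called 908 unchanged genes. Of the 10 splits, 2 gave as many as the 2215 genes with an unadjusted p under 0.05, and the highest other, which groups NC replicate 1 with CPT2 knockdown replicates 1 and 3, gave 2344, too few splits for a share under 0.05.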
